A study of Mus musculus with 8 samples.

How the data were processed

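RNA sequencing libraries of sorted mouse thymocytes were compared, 2 per group in 4 groups, with groups and replicate numbers taken from the labels. Total RNA was extracted with TRIzol, per the labels' protocols. Each deposited table holds a whole-number count per gene and an FPKM value per gene, both made by the authors. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2, featureCounts, Subread, RSEM, DESeq2 and build mm10, without roles or order. The annotation, the strand setting and which tool made each column are not given in the sources used here. Within a system the deposited FPKM divided by the count gave one constant ratio between libraries. It was close to the ratio of size factors, except for in vivo WT replicate 2 and KO replicate 1, where it lay between that ratio and the ratio of totals. No listed gene had a mean count under 5 in its system, so rows had been filtered before deposit. The tables list 12133 genes in vitro and 12665 in vivo, 11725 in both, and 11994 and 12534 symbols matched the mm10 gene annotation used for coordinates.

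The design fixed before the data were examined assumed FPKM only and named limma on log2(FPKM + 1), with edgeR on the same libraries if counts were found. The tables held counts, so the quasi-likelihood test of edgeR 4.0.16 was used (R 4.3.3, TMM normalization), on each system's 4 libraries alone, without a replicate term. Genes with FPKM of at least 1 in at least 2 libraries were tested, 9658 in vitro and 10227 in vivo. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. The difference between systems was tested over all 8 libraries as group means. SE is the absolute log2 fold change over the square root of the F statistic. Fisher exact tests of overlap were one-sided.

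Gene lists were fixed before the data were examined: T cell receptor signal, IEL precursor, cytotoxic effector, literature BCL6-repressed, egress and mature thymocyte, double-positive thymocyte, pro-apoptotic, pro-survival, proliferation, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol synthesis, cytokine and JAK-STAT, E protein and Id, follicular helper T, heat shock, mitochondrially encoded, ribosomal protein, and markers of innate-like T or NK, gamma delta T, regulatory T, B, myeloid, erythroid, early DN and stromal cells. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With 2 libraries per group, camera with an estimated correlation has few residual degrees of freedom and little power. In vitro it gave the egress list, with all 16 tested members risen, an unadjusted p of 0.0524. A list that did not pass it is therefore not shown to be unchanged. The preset test has the opposite limit, because its p-values are too small where list members vary together. In vivo the estimated correlation reached 0.955, far above 0.01. Low power is not the only reason for the gap, since fry on the same libraries passed 8 lists in vitro and 0 in vivo. The genes named are those fixed beforehand, the 10 that rose and the 10 that fell most in each system among those past the threshold without overlap of groups, up to 4 members of each list, and the 10 with the smallest adjusted p for the difference. Predicted genes, pseudogenes and receptor segments were passed over. Other genes named were chosen after their values were seen. Results for some genes and 1 pattern are not reported here.

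Total counts ranged from 14754440 to 23975636 per library. Replicates of each group differed by more than sampling noise (chi-square over degrees of freedom 9.94, 9.32, 18.9 and 10.9 for the WT and KO labels in vitro and in vivo), so none was counted as a repeat of another. The biological coefficient of variation was 0.0727 in vitro and 0.121 in vivo. The procedure was tested on simulated data with 200 changed genes. In vitro it recovered 100 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 9 false calls among 9658 genes. In vivo it recovered 85 and 98 of 100, with 17 false calls among 10227. For the difference it recovered 74 of 93 changed 2-fold and 85 of 89 changed 4-fold, with 13 false calls among 9167. The list test found the shifted list in both systems, with 1 false list in vitro and 0 in vivo. Simulated genes were drawn independently of each other, while real list members can vary together (estimated correlation 0.955 for proliferation genes in vivo). The simulation therefore does not show how often the list test passes false lists in these data.

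Alternatives were other pseudocounts, filters, scalings, limma 3.58.1 settings, DESeq2 1.42.0, a replicate block, and leaving out each library, where the lone library left in a group is assumed to vary like the others. Groups of 2 are too small for the test of outlying samples, and results under other splits of the samples were not counted. Ratios of low counts carry exact 95% binomial intervals, and a floor of 3 counts per library was used where a group was at 0.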

Results

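Gene expression was measured by RNA sequencing of mouse thymocytes that carry loxP-flanked alleles of Bcl6, a zinc-finger transcriptional repressor, with or without Cd4-cre. The labels name 4 groups of 2 libraries. In the in vitro system, CD4 and CD8 double-positive thymocytes were stimulated for 24 h with plate-bound anti-CD3 and anti-CD28, each at 8 µg/ml, and the cells that had become double-negative (DN) were then sorted. In the in vivo system, thymocytes lacking CD4 and CD8 and bearing CD5 and TCRβ were sorted directly. That gate holds the agonist-selected precursors of CD8αα intraepithelial lymphocytes (IEL). The total count per library was 23975636 and 15644567 for the in vitro libraries labelled WT and 16863477 and 20892237 for those labelled KO. In vivo it was 16022736 and 15548622 under the WT label and 14754440 and 15825507 under the KO label. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

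Bcl6, the targeted gene, lies on chromosome 16 from 23965052 to 23988852 on the minus strand of mm10. Its FPKM was 24.9 and 21.9 in the in vitro libraries labelled WT and 64.6 and 61.0 in those labelled KO. That is a log2 fold change of 1.45 (SE 0.09, n = 2 per group), against the direction of the label (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.53e-06). In vivo its FPKM was 11.5 and 13.9 under the WT label and 8.81 and 14.4 under the KO label, a log2 fold change of -0.14 (SE 0.23; edgeR adjusted p = 0.882). Gene-level counts pool all exons and cannot separate the deleted part, so Bcl6 does not check the labels in either system. Groups are therefore named by their labels throughout, and every direction below is that of the libraries labelled KO relative to those labelled WT.

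The in vitro comparison asks what the labelled loss of BCL6 changes in stimulated double-positive cells that turn DN. The libraries labelled KO had far more transcript of genes of thymic egress. Klf2, a transcription factor that drives egress (chromosome 8, 72319033 to 72321656), had a log2 fold change of 2.23 (SE 0.12, n = 2 per group), and S1pr1, the sphingosine-1-phosphate receptor it induces, of 2.40 (SE 0.14). The integrin chains Itgae and Itgb7, which pair as the receptor for epithelial E-cadherin, rose by 3.15 (SE 0.13) and 2.42 (SE 0.17). The chemokine receptor Ccr9 rose by 1.96 (SE 0.14). The inhibitory receptor Pdcd1 (chromosome 1, 94038305 to 94052553) and the orphan nuclear receptor Nr4a2, both induced by T cell receptor signalling, changed by -0.96 (SE 0.11) and -1.67 (SE 0.08). Of 9658 genes tested, 1940 rose and 1709 fell (edgeR quasi-likelihood, adjusted p under 0.05), of which 331 and 112 changed at least 2-fold. With limma on log2(FPKM + 1) 1717 rose and 1868 fell, and with limma after rescaling to TPM 1924 and 1116, so the split between directions depends on the tool and the scaling. The 2 groups did not overlap at 6812 genes, 70.5% of those tested, where chance gives 33.3% on average over splits of the libraries. Genes vary together, so a split unrelated to the label can also exceed that average.

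**Figure D1:**
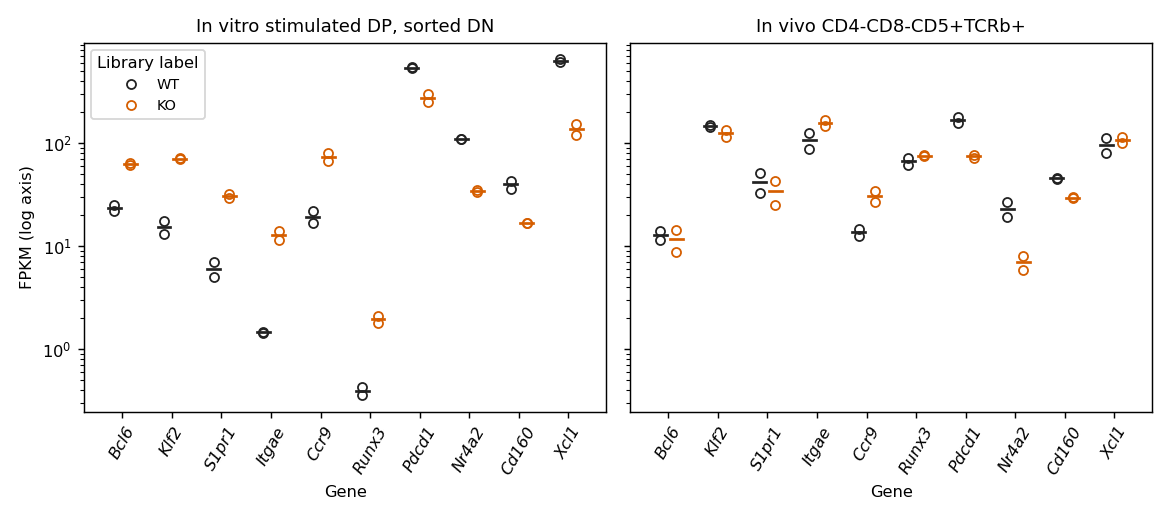
FPKM of 10 genes on a log axis in each library, with the WT-labelled libraries in black and the KO-labelled libraries in orange (circles are libraries, lines are means of 2). Bcl6 lies at 64.6 and 61.0 in the in vitro KO-labelled libraries against 24.9 and 21.9 under the WT label, and Pdcd1 and Nr4a2 lie lower under the KO label in both systems.

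All 16 tested members of the egress and mature thymocyte list rose in vitro, also when adjusted over the list alone (16), with a median log2 fold change of 1.51. These also include Il7r, the interleukin-7 receptor (1.93, SE 0.18), and the surface glycoprotein Cd52 (1.55, SE 0.09). The list passed camera (adjusted p = 8.08e-26), with adjusted p = 0.398 with an estimated correlation. Of 23 tested genes that earlier literature gives as BCL6-repressed, 17 rose and 1 fell, the same counts adjusted over the list alone, among them Selplg (1.69, SE 0.10), Gata3 (1.66, SE 0.10) and Id2 (1.89, SE 0.19). Its camera adjusted p was 1.27e-16, and adjusted p = 0.398 with an estimated correlation. Of 34 proliferation genes 24 passed the expression filter. Mki67, at FPKM 0.464 and 0.578 under the WT label and 1.97 and 1.53 under the KO label, passed it only through the KO libraries. Of the 24 tested, 18 rose and none fell, against 18 and 1 adjusted over the list alone. Those that rose include Mki67 (1.79, SE 0.18) and the replication helicase subunit Mcm5 (0.90, SE 0.08). Here camera gave an adjusted p of 2.12e-06, and adjusted p = 0.398 with an estimated correlation. Of 14 interferon-stimulated genes 8 rose and none fell, or 11 adjusted over the list alone, including the nucleic acid sensor Zbp1 (1.78, SE 0.14) and Gbp4 (1.05, SE 0.12; camera adjusted p = 0.000243, and adjusted p = 0.398 with an estimated correlation).

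The IEL precursor list went both ways in vitro. Of 16 members 9 rose and 6 fell, the same adjusted over the list alone. Besides the integrins and Ccr9, the lineage factor Runx3 rose by 2.35 (SE 0.21), while Xcl1, a chemokine for cross-presenting dendritic cells (-2.16, SE 0.11), Nkg7, a cytotoxic granule protein (-1.50, SE 0.12), and the receptor Cd160 (-1.21, SE 0.10) fell. The camera adjusted p was 0.0142, and adjusted p = 0.398 with an estimated correlation. By the preset test it was 0.0712 without WT replicate 1, 0.0979 with limma camera on log2(FPKM + 1) and 0.138 with quantile normalization, from 0.00581 to 0.398 over all settings. Of 26 T cell receptor signal genes 12 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.000123, and adjusted p = 0.398 with an estimated correlation). Besides Pdcd1 and Nr4a2, Nr4a3 (-1.21, SE 0.10), Nr4a1 (-0.65, SE 0.13) and the interleukin-2 receptor chain Il2ra (-1.98, SE 0.14) fell, and Egr3, an early response factor, rose by 1.69 (SE 0.09).

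Metabolic and stress lists were lower in the in vitro libraries labelled KO. Of 40 nuclear genes of oxidative phosphorylation 24 fell and none rose, or 25 adjusted over the list alone, with a median of -0.27 and with cytochrome c (Cycs) at -0.57 (SE 0.08; camera adjusted p = 3.94e-05, and adjusted p = 0.454 with an estimated correlation). Of 20 glycolysis genes 7 fell and 2 rose, against 8 and 2 adjusted over the list alone, with the lactate transporter Slc16a3 at -1.85 (SE 0.12). The camera adjusted p was 0.00789, and adjusted p = 0.587 with an estimated correlation, and the preset test gave 0.0584 without WT replicate 1, 0.0677 with limma camera and 0.138 with quantile normalization, from 0.000245 to 0.587 over all settings. Of 16 heat shock and dissociation stress genes 8 fell and 1 rose, the same adjusted over the list alone, with the chaperones Hspd1 at -0.91 (SE 0.10) and Hsp90aa1 at -0.72 (SE 0.10). Its camera adjusted p was 0.00392, and adjusted p = 0.398 with an estimated correlation. The list's median was -0.40 and its mean 0.21, a difference in sign that rests on Atf3. With Atf3 at its bound the median was -0.40 and the mean -0.07. Of 22 cholesterol synthesis genes 7 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.659 with an estimated correlation, and 0.195 by the preset test without WT replicate 1, from 0.00196 to 0.659 over all settings). Of 40 ribosomal protein genes 7 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.659 with an estimated correlation). The preset test gave 0.133 without WT replicate 1, 0.124 without KO replicate 1 and 0.613 with quantile normalization, from 6.69e-05 to 0.659 over all settings.

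Other lists passed upward in vitro. In the cytokine and JAK-STAT list 12 of 24 rose and 4 fell, against 12 and 5 adjusted over the list alone, with the interleukin-12 receptor chain Il12rb1 at 2.16 (SE 0.11; camera adjusted p = 0.00789, and adjusted p = 0.398 with an estimated correlation). In the E protein and Id list 4 of 8 rose and 1 fell, against 4 and 2 adjusted over the list alone, with Notch1 at 1.24 (SE 0.09; camera adjusted p = 0.00789, and adjusted p = 0.398 with an estimated correlation). Both gave 0.0543 with limma camera on log2(FPKM + 1) and 0.0553 with quantile normalization, and 0.398 was the highest value over all settings. In the innate-like T and NK list 3 of 6 rose, the same adjusted over the list alone (camera adjusted p = 0.00349, and adjusted p = 0.398 with an estimated correlation). Among double-positive thymocyte genes Dntt (-1.01), Cd24a (-0.84) and Cd8a (-0.42) fell, while Ccr4 (1.39), Cd53 (0.95), Cd8b1 (0.76) and Cd4 (0.72) were among those that rose. In that list 8 of 17 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0453, and adjusted p = 0.587 with an estimated correlation). Its preset test gave 0.119 without WT replicate 1, 0.092 without KO replicate 1, 0.0738 with limma camera and 0.123 with quantile normalization, from 0.00606 to 0.587 over all settings. Of the other tested lists, camera gave an adjusted p of 0.0504 for mitochondrially encoded genes (0 rose, 3 fell of 13, the same adjusted over the list alone) and 0.0673 for early DN thymocyte genes (4 and 2 of 6, the same adjusted over the list alone). The mitochondrial list passed downward with the replicate block (0.0213), without WT replicate 2 (0.00346) and without KO replicate 2 (0.0231), up to 0.587 over all settings. The early DN list passed upward with the replicate block (0.0243), with fry (0.0384) and without each of the 4 libraries (0.00392 to 0.0459), up to 0.398 over all settings. Camera gave 0.410 for both pro-survival genes (4 and 4 of 16, the same adjusted over the list alone) and pro-apoptotic genes (6 and 2 of 20, and 7 and 2 adjusted over the list alone). It gave 0.414 for regulatory T cell genes (4 and 3 of 10, and 4 and 4 adjusted over the list alone; the median was -0.10 and the mean 0.13). It gave 0.547 for follicular helper T genes (5 and 3 of 13, the same adjusted over the list alone) and 0.955 for cytotoxic effector genes (5 and 3 of 8, the same adjusted over the list alone). Lists with fewer than 5 tested members had no test. In these, 2 of 3 B cell genes rose, 1 of 4 myeloid genes rose and 1 fell (1 and 2 adjusted over the list alone, and the same counts as over all genes for the other lists named here), 2 of 3 thymic stroma genes and the 1 gamma delta T cell gene rose, and neither of 2 erythroid genes changed. The mitochondrial share of counts was 2.06% and 1.83% in the libraries labelled WT and 1.69% and 1.49% in those labelled KO.

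Among the 10 genes with the largest rise in vitro, Atf3, a stress-response factor, had 0 counts in both libraries labelled WT and 110 and 85 in those labelled KO, which is at least 33.4-fold higher against a floor of 3 counts per library. Zbtb7b, which encodes the CD4-lineage factor ThPOK, had 3 and 4 counts under the WT label, a ratio of 41.5 (95% counting interval 19.9 to 104), and Igfbp4 had 3 and 4, a ratio of 51.1 (24.5 to 128). These intervals and floors cover counting error only. The others were Akr1c18 (4.80, SE 0.32), Irak3 (4.75, SE 0.28), Rerg (3.35, SE 0.31), Nanp (3.32, SE 0.37), Tlr1 (3.20, SE 0.31), Itgae and Lpp (3.04, SE 0.16). The 10 with the largest fall were Capn11 (-4.09, SE 0.31), Calcb, Npw, Utf1 (-2.49, SE 0.31), Ddn (-2.49, SE 0.25), Synpo2l (-2.38, SE 0.26), Lox (-2.34, SE 0.29), Avpr1a (-2.27, SE 0.17), Xcl1 and Penk (-2.15, SE 0.57). Capn11, below the expression filter in vivo, had 15 counts there under the WT label and 158 under the KO label, a KO-to-WT ratio of 11.0 (6.47 to 20.1) in the opposite direction. For Calcb, with 6 and 3 counts under the KO label, the WT-to-KO ratio was 7.89 (3.94 to 17.9), and for Npw, with 1 and 3 counts, 6.96 (2.44 to 27.2). Penk lost its call with DESeq2, robust edgeR, robust limma and the fit of all 8 libraries.

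Of the genes fixed for naming, Bcl2, the survival factor, rose by 0.96 (SE 0.10) in vitro, Il2rb by 0.91 (SE 0.08), Id3 by 0.77 (SE 0.11), Cd8b1 by 0.76 (SE 0.21) and Cd4 by 0.72 (SE 0.09). Ikzf2 fell by 0.69 (SE 0.11) and Cd8a by 0.42 (SE 0.10). The Cd8b1 call was lost without WT replicate 1 and without KO replicate 1, and the Cd8a call without WT replicate 2, with TPM and with all 8 libraries in the fit. Egr2 (0.19, SE 0.09), Bcl2l11 (0.12, SE 0.09), Cd5 (0.07, SE 0.11), Cd69 (0.06, SE 0.08) and Mcl1 (0.02, SE 0.09) did not pass. Prdm1, Cdkn1a and Zbtb16 were below the expression filter (Prdm1 had 2 counts under the WT label and 56 under the KO label, a ratio of 29.2 with a 95% counting interval of 7.71 to 247), and Tbx21, Gzma, Gzmb and Ccl5 had no row in the in vitro files.

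The in vivo comparison asks the same of the agonist-selected DN cells in the animal. In the libraries labelled KO, Il23r (chromosome 6, 67422932 to 67491855) and Il1r1, receptors for interleukin-23 and interleukin-1, changed by -2.81 (SE 0.36, n = 2 per group) and -2.39 (SE 0.34). The inhibitory receptors Lag3, Tigit and Pdcd1 changed by -2.23 (SE 0.17), -2.02 (SE 0.21) and -1.18 (SE 0.12), and Nr4a2 by -1.75 (SE 0.22). The pro-apoptotic factor Bmf changed by -1.37 (SE 0.14), the growth factor receptor Kit by -2.05 (SE 0.28), Id3 by -0.82 (SE 0.12) and Cd160 by -0.63 (SE 0.09). Ccr9 rose by 1.14 (SE 0.15), and the inducible heat shock genes Hspa1a and Hspa1b by 2.32 (SE 0.22) and 2.46 (SE 0.24); these near-identical paralogs share reads, so the split between them is uncertain. Of 10227 genes tested, 29 rose and 84 fell (edgeR quasi-likelihood, adjusted p under 0.05), of which 20 and 70 changed at least 2-fold, and 1445 had an unadjusted p under 0.05. The groups did not overlap at 4453 genes, 43.5%, where chance gives 33.3% on average over splits of the libraries. Because genes vary together, a split unrelated to the label can also exceed that average, so 43.5% is no evidence of a label effect by itself. The count of genes past the threshold depends on single libraries and on the tool. It was 7 without WT replicate 2, 21 without KO replicate 1, 191 without WT replicate 1, 279 without KO replicate 2, 505 with DESeq2 and 68 with limma on log2(FPKM + 1), and all 113 genes kept their direction in each of these fits. The split between directions was not stable either, with 193 risen and 86 fallen without KO replicate 2, 260 and 245 with DESeq2, 266 and 279 with all 8 libraries in one fit, and 607 and 471 with the replicate block.

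The 10 genes with the largest rise in vivo were Hspa1b, Hspa1a, Hmga2 (2.04, SE 0.24), Syt13 (1.95, SE 0.19), Cdh3 (1.93, SE 0.27), Slc22a3 (1.75, SE 0.25), F13a1 (1.52, SE 0.19), Itsn1 (1.51, SE 0.20), Slc16a5 (1.42, SE 0.21) and Igfbp4 (1.40, SE 0.11). The 10 with the largest fall were Myl1, Avpr1a (-3.72, SE 0.48), the heparan sulfate proteoglycan Sdc1 (-3.41, SE 0.33), Pxdc1 (-3.32, SE 0.40), Fam83a (-3.26, SE 0.46), Kcnc1 (-2.94, SE 0.26), Napb (-2.93, SE 0.30), Greb1 (-2.92, SE 0.35), Il23r and Kif5c (-2.78, SE 0.40). Myl1 had 2 and 4 counts under the KO label, and the WT-to-KO ratio was 24.1 (95% counting interval 10.8 to 66.7). Of the fixed genes, Gzmb (1.30, SE 0.27), Cd8b1 (1.34, SE 0.32), Gzma (1.08, SE 0.33) and Ikzf2 (-1.12, SE 0.25) had large changes that did not pass. Klf2 (-0.24, SE 0.11), S1pr1 (-0.32, SE 0.30), Itgae (0.54, SE 0.19), Itgb7 (0.19, SE 0.13), Runx3 (0.16, SE 0.11), Zbtb7b (0.47, SE 0.17), Il7r (0.15, SE 0.14), Il2rb (-0.18, SE 0.12), Id2 (0.20, SE 0.19), Tbx21 (0.25, SE 0.23) and Prdm1 (0.46, SE 0.21) did not pass. Neither did Xcl1 (0.15, SE 0.17), Ccl5 (0.30, SE 0.25), Zbtb16 (0.18, SE 0.24) and Bcl2 (-0.07, SE 0.17). The remaining fixed genes Bcl2l11 (-0.09, SE 0.23), Mcl1 (-0.24, SE 0.12), Egr2 (-0.41, SE 0.16), Nr4a1 (-0.84, SE 0.30), Cd69 (0.01, SE 0.27), Cd5 (0.07, SE 0.24), Cd8a (0.18, SE 0.49) and Cd4 (0.30, SE 0.58) did not pass either, and Cdkn1a was below the filter. With the replicate block, Gzmb, Cd8b1, Gzma, Ikzf2, Itgae, Zbtb7b, Egr2 and Nr4a1 passed with unchanged direction, as did Mki67, Cenpf, H2-Eb1, Ms4a1, Dntt, Rag1 and Sqle of the lists below. Of the 144 genes that met the naming rule, 62 gained a call with the block and none lost one. Cd4 differed within each label, with FPKM 26.8 and 54.96 in the libraries labelled WT and 22.8 and 78.4 in those labelled KO. Under both labels it was higher in replicate 2.

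**Figure D2:**
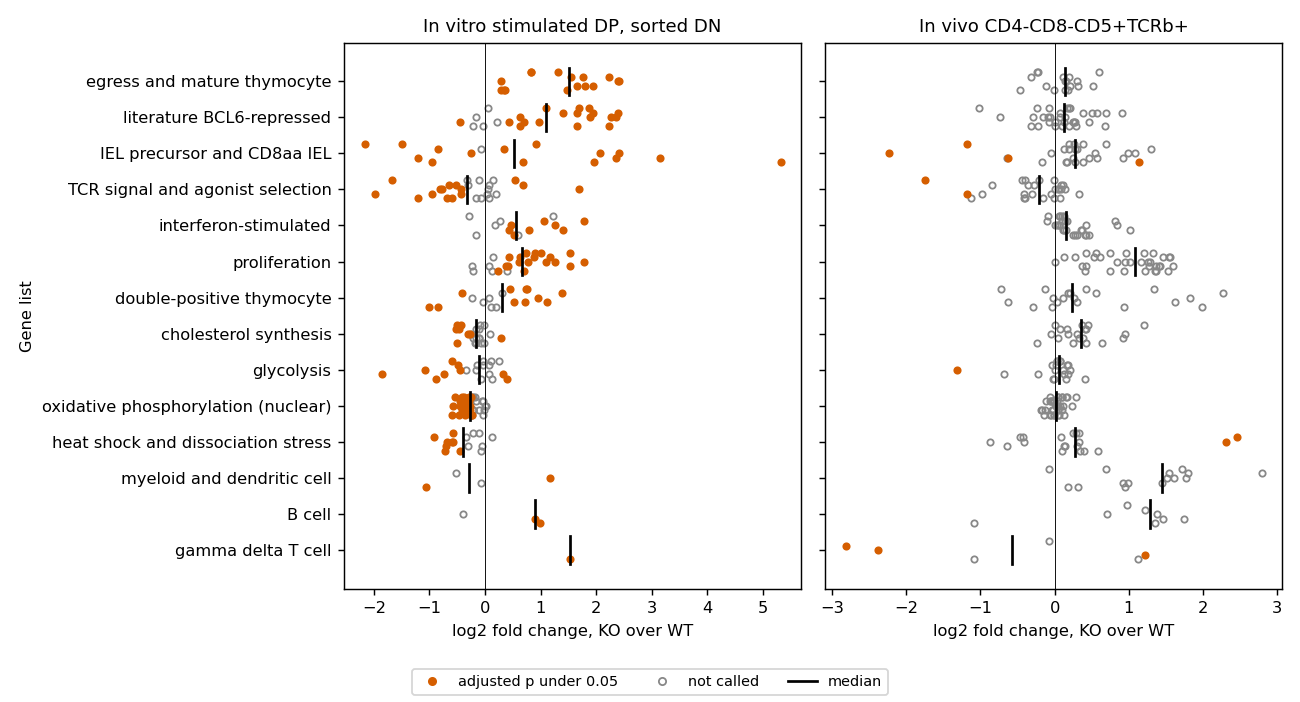
Log2 fold change (KO label over WT label) of each tested member of 14 gene lists in each system. Filled points have an adjusted p under 0.05, open points do not, and bars are list medians over all members; Atf3, at 0 counts in both in vitro libraries labelled WT, is not drawn. All 16 egress and mature thymocyte genes lie above 0 in vitro, and 33 of 34 proliferation genes lie above 0 in vivo with none called.

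Proliferation genes were higher together in vivo without any member passing alone. Of 34 members 33 had a positive fold change, with a median of 1.09 (0.62 without KO replicate 1) and with Mki67 at 1.32 (SE 0.27) and Cenpf at 1.55 (SE 0.28). None passed over all genes and 27 did adjusted over the list alone (camera adjusted p = 1.13e-22, and adjusted p = 0.701 with an estimated correlation). The same libraries had higher levels of markers of other cells. Of 15 myeloid and dendritic cell genes 14 had a positive fold change, with a median of 1.45 and with the class II chain H2-Eb1 at FPKM 13.6 and 4.86 under the WT label and 45.8 and 15.1 under the KO label. None passed over all genes and 1 did adjusted over the list alone (camera adjusted p = 4.97e-05, and adjusted p = 0.701 with an estimated correlation). The median was 0.23 without KO replicate 1, where the preset test gave 0.108 (from 2.45e-24 to 0.701 over all settings), 0.84 without WT replicate 2 and 2.54 without WT replicate 1. Of 8 B cell genes 7 were positive, with a median of 1.28 and with Ms4a1 at 1.74 (SE 0.59), and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.00351, and adjusted p = 0.701 with an estimated correlation). Without WT replicate 2 that median was 0.59 and the preset test gave 0.104 (from 9.33e-13 to 0.701 over all settings), and without WT replicate 1 it was 2.48. In the double-positive thymocyte list 14 of 20 were positive, with Dntt, the enzyme that adds N nucleotides, at 1.98 (SE 0.39) and the recombinase gene Rag1 at 2.26 (SE 0.47). None passed over all genes, and 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00432, and adjusted p = 0.701 with an estimated correlation, and 0.142 by the preset test without WT replicate 1, from 1.17e-06 to 0.701 over all settings).

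T cell receptor signal genes were lower in vivo, with 2 of 27 fallen over all genes (Nr4a2 and Pdcd1), 4 adjusted over the list alone, and a median of -0.21. The camera adjusted p was 7.27e-05, and adjusted p = 0.701 with an estimated correlation. Without KO replicate 1 the median was 0.06 and the preset test gave 0.209, from 5.21e-11 to 0.701 over all settings. The median was -0.39 without KO replicate 2 and -0.14 without WT replicate 2. Heat shock and dissociation stress genes were higher, with 2 of 20 risen (Hspa1a and Hspa1b) and 4 adjusted over the list alone (camera adjusted p = 0.000555, and adjusted p = 0.701 with an estimated correlation). The preset test gave 0.744 without WT replicate 2 and 0.0784 without KO replicate 2, and 1.17e-06 was the lowest value over all settings. Cholesterol synthesis genes had a median of 0.35, with the squalene epoxidase Sqle at 0.95 (SE 0.24), none of 20 passing over all genes and 6 adjusted over the list alone (camera adjusted p = 4.97e-05, and adjusted p = 0.701 with an estimated correlation). Interferon-stimulated genes had a median of 0.15, with none of 28 passing over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.701 with an estimated correlation, and 0.0729 by the preset test without WT replicate 2, from 2.46e-06 to 0.701 over all settings). That median was 0.31 without WT replicate 1 and 0.08 without WT replicate 2. In the IEL precursor list 1 rose (Ccr9) and 3 fell (Lag3, Pdcd1 and Cd160) of 27, against 4 and 3 adjusted over the list alone (camera adjusted p = 0.0272 upward, and adjusted p = 0.701 with an estimated correlation, and 0.282 by the preset test without WT replicate 2, from 1.5e-08 to 0.701 over all settings).

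Other lists also passed in vivo. Cytotoxic effector genes were higher, with none of 19 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.779 with an estimated correlation, and 0.674 by the preset test without WT replicate 2, from 8.59e-17 to 0.779 over all settings). In the E protein and Id list, which passed upward, 1 of 11 fell (Id3), and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.701 with an estimated correlation, and 0.183 by the preset test without WT replicate 2, from 2.85e-07 to 0.701 over all settings). In the follicular helper T list, which passed downward, 2 of 16 fell (Tigit and Pdcd1), and 3 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0356, and adjusted p = 0.701 with an estimated correlation). Its preset test gave 0.0906 without KO replicate 1, 0.121 without KO replicate 2, 0.176 with limma camera and 0.227 with quantile normalization, from 0.0112 to 0.701 over all settings. The gamma delta T cell list did not pass (camera adjusted p = 0.192), although Il23r and Il1r1 fell and the factor Etv5 rose by 1.21 (SE 0.15) among its 6 members, with 2 higher and 3 lower adjusted over the list alone. It passed downward with the replicate block (0.000444), without WT replicate 2 (0.0116) and without KO replicate 1 (1.17e-06), up to 0.857 over all settings. Its median of -0.58 ranged from -1.06 to -0.18 on leaving out one library. Camera gave an adjusted p of 0.144 for BCL6-repressed genes (none of 33 passing, and 2 higher and 1 lower adjusted over the list alone) and 0.176 for pro-apoptotic genes (1 of 22 fallen, also adjusted over the list alone). It was 0.186 for early DN thymocyte genes (1 of 11 fallen, and 4 higher and 2 lower adjusted over the list alone) and 0.193 for egress and mature thymocyte genes (none of 17, also adjusted over the list alone). It gave 0.485 for both mitochondrially encoded genes (none of 13, also adjusted over the list alone) and regulatory T cell genes (none of 12, and 1 lower adjusted over the list alone), and 0.488 for the cytokine and JAK-STAT list (none of 30, and 2 higher and 2 lower adjusted over the list alone). It gave 0.792 for oxidative phosphorylation (none of 40, also adjusted over the list alone) and 0.802 for innate-like T and NK cell genes (none of 15, and 2 higher and 1 lower adjusted over the list alone; the median was 0.18 and the mean -0.01). It gave 0.9496 for glycolysis (1 of 20 fallen, also adjusted over the list alone; the median was 0.05 and the mean -0.03), and 0.994 for both ribosomal protein genes (none of 40, also adjusted over the list alone) and pro-survival genes (none of 17, and 1 lower adjusted over the list alone). Some of these lists passed under other settings. BCL6-repressed genes passed upward without WT replicate 1 (0.0163) and without KO replicate 1 (0.00625), egress genes upward without KO replicate 1 (0.00342), and innate-like genes upward without WT replicate 1 (0.0163). Early DN genes passed upward with quantile normalization and limma camera (0.0437) and without KO replicate 2 (0.0102), and regulatory T cell genes downward with the replicate block (0.0172) and without KO replicate 2 (0.00186). Ribosomal protein genes passed upward without WT replicate 1 (0.00277) and downward without WT replicate 2 (0.000802). The erythroid list with 1 tested member and the thymic stroma list with 4 had no test and no member that passed over all genes (1 of the stroma genes was lower adjusted over the list alone). The mitochondrial share of counts was 2.08% and 2.24% under the WT label and 1.89% and 1.94% under the KO label.

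The difference between the fold changes of the systems was tested in all 8 libraries, since a gene past the threshold in one system and not in the other is not thereby shown to differ. The egress factor Klf2 had a fold change lower in vivo than in vitro by 2.43 on the log2 scale (in vivo minus in vitro -2.43), the glycosyltransferase Lfng by -2.58, Prr5l by -3.41, Egr3 by -1.58, Anxa6 by -2.13, the TGF-β mediator Smad3 by -1.61, Igfbp4 by -4.19, Art2b by -2.88, Tlr1 by -3.22 and Cyth4 by -1.85. These are the 10 with the smallest adjusted p in the edgeR quasi-likelihood test, which ranged from 0.000151 to 0.000228. For Igfbp4, with 3 and 4 counts under the in vitro WT label, the fitted value is imprecise, and with quantile normalization of log2(FPKM + 1) and limma it was 0.11. Its FPKM under that label was 0.028 and 0.055, so adding 1 before the log shrinks the in vitro fold change. With limma on log2(FPKM + 1), 1 of the 10 genes lost its call, and with pseudocount 0.1 all 10 kept direction and call. Of 9364 genes tested, the in vivo fold change was above the in vitro one for 615 and below it for 919. The total of 1534 became 533 without in vitro WT replicate 1, 773 without in vitro KO replicate 1, 851 without in vitro KO replicate 2 and 832 without in vivo KO replicate 1. Of the 22 lists tested for a difference by camera, 12 passed, with a median difference of -1.22 for the egress list (adjusted p = 2.54e-16, and adjusted p = 0.138 with an estimated correlation) and -1.003 for the BCL6-repressed list (adjusted p = 2.81e-12, and adjusted p = 0.138 with an estimated correlation). No list passed with an estimated correlation, where 0.138 was the smallest adjusted p, but that version has little power with 2 libraries per group. The labels name a different sequencing provider for each system, which cancels here only if it acts alike on both genotype labels.

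Across genes, the fold changes of the 2 systems had a Pearson correlation of 0.231 and a Spearman correlation of 0.0748 over 9364 genes, which are not independent replicates. Genes called in both systems numbered 51, of which 42 changed in the same direction. Pdcd1, Nr4a2, Lag3, Cd160, Tigit and the enolase Eno3 fell in both, and Ccr9, Etv5 and Igfbp4 rose in both. Of 13 genes that rose in vivo and were tested in both systems, 12 also rose in vitro, where independent lists give 2.65 (one-sided Fisher exact test, p = 5.26e-08), and of 54 such genes that fell in vivo 30 fell in vitro, where independent lists give 9.46 (p = 2.88e-10). Both Fisher p-values treat genes as independent draws, which they are not, so they are likely too small. The other 9 of these 51 changed in opposite directions, and all 9 rose in vitro and fell in vivo. They include Kit (1.52, SE 0.22 in vitro), Art2b (0.80, SE 0.09 in vitro), Prr5l (0.70, SE 0.15 in vitro) and Id3.

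**Figure D3:**
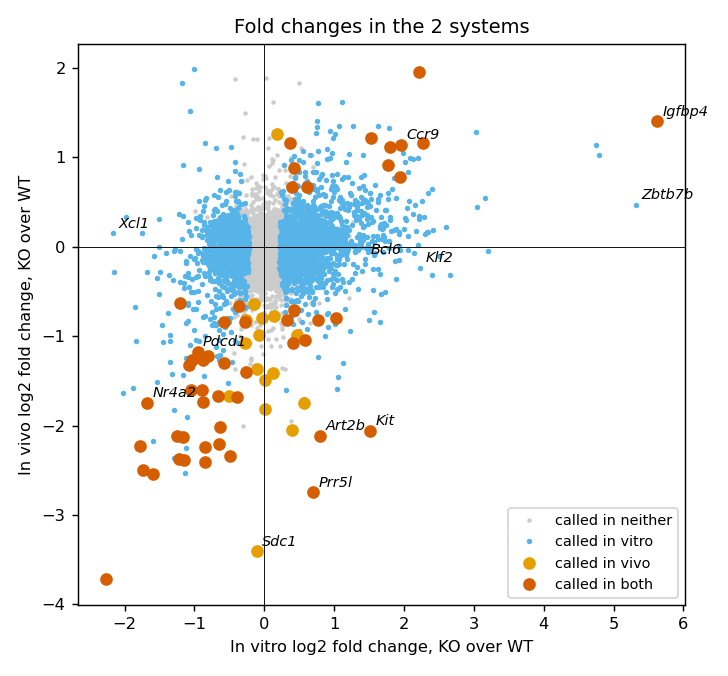
Log2 fold change (KO label over WT label) in vitro on the horizontal axis and in vivo on the vertical axis for genes tested in both systems, coloured by where the adjusted p is under 0.05. Atf3 is not drawn. Pdcd1 and Nr4a2 lie low in both systems, and Kit, Art2b and Prr5l lie right of 0 and below it.

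Levels in the 2 systems are given side by side without a test, because system and library provider cannot be told apart. Runx3 was at 0.393 ± 0.050 FPKM (SD, n = 2) in the in vitro libraries labelled WT and 66.6 ± 6.86 in the in vivo ones, Zbtb7b at 0.033 ± 0.015 and 36.8 ± 0.450, Id2 at 1.83 ± 0.463 and 249 ± 68.7, Itgae at 1.45 ± 0.023 and 107 ± 27.3, and Klf2 at 15.3 ± 3.08 and 146 ± 4.42. Xcl1 was at 627 ± 29.6 and 96.0 ± 22.6, and Pdcd1 at 539 ± 11.4 and 167 ± 15.9.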

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

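All tests of explanations here were chosen only after the result was seen. Each gene or list of this paragraph is given because the test over all 8 libraries found its fold change to differ between the systems. Of 77 named genes tested in both, 52 differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Over all genes 1534 of 9364 did. Many of the named genes were chosen for large changes, or for this difference itself, so their larger share follows from the choice and is no result. In vivo minus in vitro, the log2 fold change was lower for Akr1c18 (-3.74), Anxa6 (-2.13), Art2b (-2.88), Atf3 (-7.94), Igfbp4 (-4.19), Irak3 (-3.59), Itgae (-2.59), Itgb7 (-2.20), Kit (-3.54), Klf2 (-2.43) and Lfng (-2.58). The same held for Lpp (-2.56), Prr5l (-3.41), Runx3 (-2.16), S1pr1 (-2.68), Sdc1 (-3.28), Tlr1 (-3.22) and Zbtb7b (-4.82). It was also lower for Bcl2 (-1.01), Bcl6 (-1.56), Bmf (-1.23), Ccr9 (-0.79), Cd52 (-1.41), Ctsw (-1.33), Cyth4 (-1.85) and Egr3 (-1.58). Others below were Gata3 (-1.05), Gbp4 (-0.86), Id2 (-1.67), Id3 (-1.56), Il12rb1 (-1.96), Il2rb (-1.07) and Il7r (-1.76), and further Lag3 (-1.35), Notch1 (-0.64), Selplg (-1.54), Smad3 (-1.61), Tigit (-1.36) and Zbp1 (-1.69). It was higher for Cd160 (0.60), Cox7b (0.54), Cycs (0.83), Cyp51 (1.17), Dntt (3.01), Hsp90aa1 (1.32), Hspd1 (1.28), Il2ra (2.34), Nkg7 (1.83), Slc16a1 (1.30), Slc16a3 (1.20), Sqle (1.40) and Xcl1 (2.34). The Atf3, Igfbp4 and Zbtb7b values rest on 0 to 4 counts under the in vitro WT label and are no precise size. Among lists the median difference was negative for egress and mature thymocyte (-1.22), literature BCL6-repressed (-1.0), IEL precursor and CD8aa IEL (-0.93), iNKT and innate-like T or NK cell (-0.93), interferon-stimulated (-0.35), follicular helper T (-0.46) and cytokine and JAK-STAT (-0.18), and positive for cholesterol synthesis (0.56), oxidative phosphorylation (nuclear) (0.33), heat shock and dissociation stress (0.42), ribosomal protein (0.18) and glycolysis (0.11), none of them passing with an estimated correlation (smallest adjusted p = 0.138).

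Bcl6 counts were higher in the in vitro libraries labelled KO. Swapped labels in vitro alone cannot be told apart. Of 67 genes called in vivo, 76.1% had the same sign in vitro, which counts against a swap only if genotype acts alike in both systems. The fold changes had a Spearman correlation of 0.0748 over all genes, which are not independent. A swap in both systems cannot be told apart by the BCL6-repressed list, whose median was 1.10 in vitro and 0.13 in vivo, where the list did not pass. Reads from exons outside the deleted part could keep Bcl6 counts up under the KO label. By themselves they would not lift them above the WT label, so with right labels the 1.45 log2 rise would also need more transcript. The share of such reads stays open because the counts pool exons. No biological explanation was tested.

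Proliferation genes had positive fold changes in the in vivo libraries labelled KO (33 of 34), as did 14 of 20 double-positive thymocyte genes. In the main fit no member passed over all genes at an adjusted p under 0.05. At the looser threshold of 0.1, Cenpf (0.0683), Mki67 (0.0977), Arpp21 (0.0734) and Dntt (0.088) passed (edgeR quasi-likelihood test). Members also passed with the replicate block, among them Mki67, Cenpf, Dntt and Rag1. Neither list passed camera with an estimated correlation (adjusted p = 0.701). Over the 24 proliferation and 17 double-positive genes tested in both systems, neither list differed by camera (adjusted p = 0.4985 and 0.8909). Dntt itself differed, with a log2 fold change of -1.01 in vitro and 1.98 in vivo (edgeR quasi-likelihood, adjusted p = 0.00316). KO replicate 1 alone is argued against for the proliferation list, whose median was 0.62 without it. Double-positive cells in the gate, which excludes CD4 and CD8, cannot be told apart for Dntt. Its log2 fold change exceeded that of Cd8a by 1.81 (SE 0.62), of Cd4 by 1.69 (SE 0.69) and of Cd8b1 by 0.64 (SE 0.51). These SEs treat the genes as independent although they come from the same libraries. Admixed cells add transcript, so each fold change also depends on the gene's level in the gated cells. Mean FPKM under the WT label was 11.5 for Dntt, 40.9 for Cd4, 2.05 for Cd8a and 4.47 for Cd8b1. The excess in fold change therefore cannot decide. KO replicate 1 had the highest Dntt and the lowest Cd8a and Cd4 of the 4 libraries. For Cd8b1 the FPKM was 7.82 in KO replicate 1 and 14.9 in KO replicate 2, where Dntt was at 62.1 and 29.4. That order is opposite, but both Cd8b1 values lie above those under the WT label (4.03 and 4.90). Early DN thymocytes, which a gate on CD5 and TCRβ would largely leave out, may contribute and stay open. The 10 early DN genes outside the double-positive list had a median of 0.31. The SE of their mean was 0.35, taken over genes, so it does not measure the spread between libraries. The 1 that passed, Kit, fell (-2.05). In the full list of 11, 9 fold changes were positive and 2 negative, those of Kit and Lyl1 (-1.62, not passing). An effect of genotype on cycling was not tested apart from these.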

How the results depend on the processing

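The DESeq2, RLE, unnormalized, robust edgeR and crossed-pairing tests were chosen only after the data were seen, as was the use of the design's limma test on log2(FPKM + 1) as an alternative to edgeR. The count of genes in vitro stayed within 1.5 times its value under every alternative run, and the correlation between systems ranged from 0.177 to 0.297. The 113 in vivo genes became 68 with limma on log2(FPKM + 1), and with limma also 75 and 74 with pseudocounts 0.1 and 0.5, 45 with TPM, 38 with quantile normalization and 70 with robust eBayes. They became 52 with FPKM of at least 5 (fewer genes were tested), 250 at an adjusted p under 0.1, 505 with DESeq2 and 545 with all 8 libraries in one fit. They ranged from 7 (without WT replicate 2) to 279 (without KO replicate 2) on leaving out one library. The 1534 genes of the difference ranged from 533 to 1816. In vitro, 15 lists became 0 with an estimated correlation, 8 with fry, 10 with limma camera on log2(FPKM + 1) and 9 with limma camera after quantile normalization; in vivo, 12 became 0 with an estimated correlation and 0 with fry. Where not named, the cause was not tested. Igfbp4 reversed in the difference (0.11, quantile normalization of log2(FPKM + 1)), and Hbb-bs in vitro ranged from -1.61 to 2.59 over the libraries left out. Of 2565 values of named genes in vitro, 2496 kept direction and side of the threshold, 45 lost and 22 gained a call and 2 reversed; of 2827 in vivo, 2498 kept both, 146 lost and 183 gained a call; of 147 for the difference, 144 kept both, 2 lost the call and 1 reversed. Replicate numbers are shared by label only, and same-numbered deviations correlated at -0.305 in vitro and 0.459 in vivo. The second principal component in vivo (23.5% of variance) set replicate 1 (15.6 WT, 7.90 KO) apart from replicate 2 (-7.89 WT, -15.6 KO) under both labels. In vitro (10.4%) it set WT replicate 1 and KO replicate 2 apart from WT replicate 2 and KO replicate 1. The labels do not say what same-numbered libraries share, so the in vivo counts without a block leave this axis in the spread. With the replicate block the counts were 3159 in vitro, 1078 in vivo and 1796 for the difference, with 17 and 14 lists. Crossing the pairs gave 4997 genes in vitro. Depth limits genes with few counts, such as Igfbp4 and Zbtb7b in vitro.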

Other observations

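Further genes of the lists changed in vitro in the libraries labelled KO. Ctsw, a protease of cytotoxic lymphocytes, rose by 1.46 on the log2 scale. The lactate transporter Slc16a1 fell by 0.87, and Cyp51 and Sqle, enzymes of sterol synthesis, fell by 0.50 and 0.42.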
